A study of Mus musculus with 38 samples.

How the data were processed

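Whole-lung RNA from 38 female C57BL/6 mice was measured on 38 Agilent mouse expression arrays, with lung RNA in the red channel (Cy5) and a universal mouse reference RNA made from 11 cell lines in the green channel (Cy3). Per the labels, the mice received vehicle or cube-shaped titanium dioxide nanoparticles by a single intratracheal instillation of 40 µl, and lungs were taken 1 or 28 days later. Per the labels, RNA with an integrity number above 7 was used, at 200 ng per array. The labels give each array its own sample number and do not state in so many words that each array is a separate mouse; the arrays were treated as separate mice.

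Per the file headers, the deposited spot files hold the median intensity of each spot and of its local background in both channels, as read by Agilent Feature Extraction 11.0.1.1 with no normalization between arrays. The deposited value table, made by the authors, holds log2 ratios of red over green for each probe, with column medians from -0.0348 to -0.0109; the labels do not state how it was normalized. Across probes, its columns correlated with the loess ratios computed here at r from 0.984 to 0.996, and with loess ratios made without background correction at r from 0.992 to 0.998 (probes are not independent replicates). The spot files were used for the comparisons and the authors' table only as an alternative.

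Ratios were computed with limma 3.58.1 in R 4.3.3 (packages data.table, version 1.17.8, and statmod, version 1.5.0). Median signals were background corrected by normexp with an offset of 50, and log2 ratios of red over green were loess normalized within each array. Of 59305 spots that were not controls, those marked as non-uniform or population outliers in either channel were left out (185 to 313 per array); 0 red spots were saturated. Spots of the same probe were averaged, giving 55681 probes. A probe was tested when its red signal was well above background on at least 4 arrays of at least 1 group, which 28438 probes met. Where several probes measured the same gene (4937 genes), the probe with the highest mean red signal stood for it. This left 21639 genes, of which 14484 carried a symbol and 7155 were transcript entries without a symbol.

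A linear model with the 8 groups of dose and day and with the slide (5 levels) as a fixed block was fitted to all 38 arrays, leaving 26 residual degrees of freedom and 3.39 prior degrees of freedom. Moderated tests were two-sided and were adjusted by Benjamini-Hochberg over the 21639 genes within each of 14 contrasts, with a threshold of 0.05; about 1082 genes would lie under an unadjusted p of 0.05 by chance. Errors of fold changes are standard errors (SE) from limma. Of 37 gene lists, 36 had at least 3 tested members and were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and by themselves with fry, adjusted over the lists within a contrast; the thymus list had 2 tested members and was not tested. For list tests 121 missing values were filled from the model. Counts adjusted over the list alone used the same moderated p-values.

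Genes were named by a rule: a symbol, an adjusted p under 0.05 and the same sign of the difference on every slide that held both groups. At 162 µg against 0 µg on each day these were the 10 highest and 6 lowest fold changes, together with up to 3 members of each list past the threshold. In every other contrast the 3 highest and 3 lowest were taken. For genes named by this ranking, agreement over slides was required by the rule and is no further result. From lists called by camera, up to 4 members with the lowest p were given as examples, chosen after their values were seen; other genes chosen that way are pointed out where they appear. The model, threshold, lists, contrasts, rule for named genes and most alternative settings were chosen before the data were examined.

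Some steps differed from the plan. The plan named mean spot signals, but the spot files hold median signals, which were used. The files carry no gene names, so RefSeq identifiers on the array were matched to symbols by name only (28026 probes), and older names in the gene lists were looked up as synonyms. The array design header names build mm9 and the RefSeq table another build, so no coordinates are given. An array at 162 µg (replicate 5 of day 28) has a title that says day 1 and a time label that says day 28; it was placed at day 28 by its time label, its position on the slide and its sample number, and the alternative placement was run.

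Each slide held nearly 1 array of every group, so dose was compared within slides. Day follows the position on the slide, so a day effect and a position effect cannot be told apart where control lungs are compared between days. In differences between days of the response to a dose, a position effect common to all doses cancels. The same dyes were used on every array without a dye swap, so differences between groups compare lung with lung, while a ratio on its own carries any dye bias. Array depth is given as the number of red spots well above background; the number of arrays limits the precision.

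The fit was tested on simulated data, with changes added to independent normal noise of the spread estimated for each gene. At 162 µg on day 1, 40.3% of genes changed by 0.5 (log2), 94% of those changed by 1 and 98.5% of those changed by 2 were called, with 7 false calls. At day 28 these shares were 52.2%, 88.1% and 98.5%, with 3 false calls. A list shifted by 0.5 was called on both days with 0 other lists called. The simulated noise does not hold the shared other-tissue signal that some real arrays do. It is also independent between genes, so it cannot test list calls at the preset correlation where real members of a list vary together.

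Alternatives planned in advance were: no slide block, the slide as a random block, no background correction, Agilent's processed signals, quantile normalization of the average intensity, no filter on dim probes, only probes above background on all arrays, the mean of a gene's probes, the authors' table, calls that were also 1.5-fold, only the groups compared, the array with conflicting labels placed at day 1, robust moderation with a trend, an estimated correlation for lists, and leaving out each array in turn. After seeing the data, 5 more were added: leaving out the 8 arrays whose skeletal muscle list mean lay above 2 (log2), the muscle list mean as a covariate, the muscle and squamous epithelium list means as covariates, leaving out 9 arrays with a first principal component above 25, and array weights. The marker lists for squamous epithelium, a second set of muscle genes, brown fat, chaperones and the arms of the clock were also chosen once the data had been seen.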

Results

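Gene expression in the lung was measured on 38 two-colour arrays from female C57BL/6 mice 1 or 28 days after a single instillation of 0, 18, 54 or 162 µg of cube-shaped titanium dioxide nanoparticles. Groups held 5 arrays each, except the 54 µg groups, which held 4 on each day. The number of red spots well above background ran from 21661 to 34887 at 0 µg, 24551 to 34515 at 18 µg, 22500 to 45574 at 54 µg and 24951 to 34367 at 162 µg on day 1. On day 28 it ran from 23773 to 32814 at 0 µg, 23575 to 34256 at 18 µg, 21428 to 34998 at 54 µg and 21565 to 32324 at 162 µg. The 8 arrays of slide 2 were the dimmest, with 21428 to 24951 such spots. Changes below are log2 fold changes with their SE from limma, and n is the number of arrays per group. The number of arrays limits the precision: the median SE of a gene was 0.119 for 5 against 5 arrays and 0.128 where a group had 4.

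Skeletal muscle genes, which lung tissue should hold little of, were high on 8 of the 38 arrays. On these 8 arrays the mean log2 ratio of the 6 measured skeletal muscle genes lay between 3.81 and 5.44, against -0.67 to 1.17 on the other 30 arrays. They were 3 of the 5 control arrays, 2 of the 5 at 18 µg and 2 of the 4 at 54 µg on day 1, and 1 of the 4 at 54 µg on day 28. None of the 5 arrays at 162 µg on day 1, nor any of the other day 28 groups, was among them. On 6 of the 8, genes of keratinised squamous epithelium (11 measured, a list drawn up once the data had been seen) also lay above the cutoff of 2. Adipose and heart muscle genes varied between arrays in most groups. The adipose mean was 4.63 ± 1.41 (SD, n = 4) at 54 µg and 3.32 ± 1.91 (SD, n = 5) at 0 µg on day 1. The first principal component held 36.6% of the variance.

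**Figure D1:**
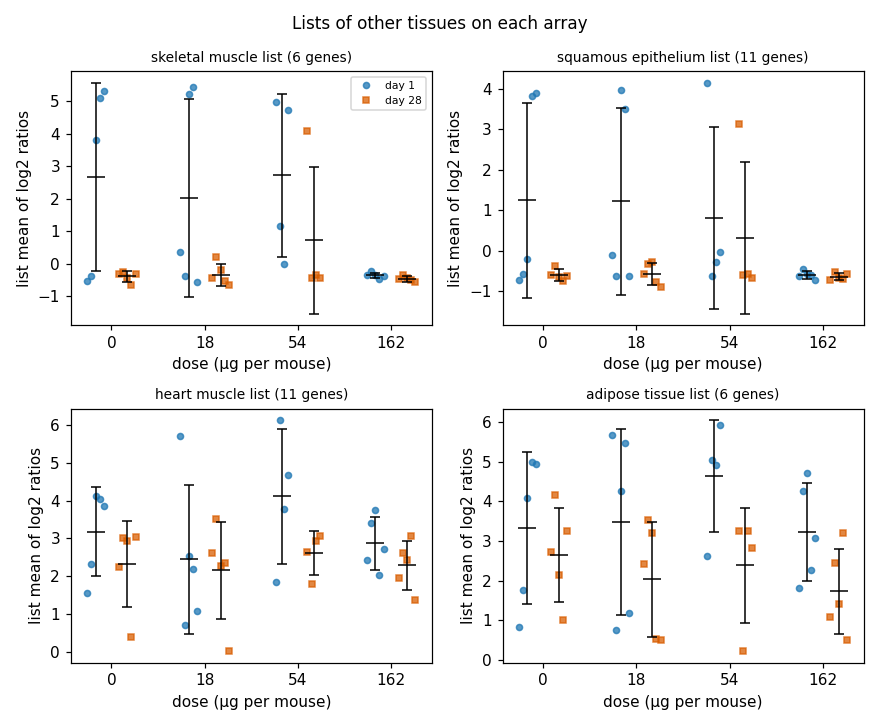
Mean log2 ratio of lung over reference for skeletal muscle, squamous epithelium, heart muscle and adipose genes on the y axes against dose in µg per mouse on the x axes, with a dot per array (day 1 blue circles, day 28 orange squares) and bars of the mean ± SD. The 5 arrays at 162 µg on day 1 had skeletal muscle means from -0.48 to -0.24, whereas the day 1 controls ranged from -0.53 to 5.32.

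The acute response to the highest dose was compared with vehicle at day 1. Slc26a4 (NM_011867), the anion exchanger pendrin of airway epithelium, rose by 2.09 ± 0.35 (adjusted p = 0.0335), from a log2 ratio of 1.67 ± 0.31 in controls to 3.76 ± 0.89 at 162 µg (SD, n = 5 each). Noxo1 (NM_027988), an organizer subunit of the NADPH oxidase NOX1, rose by 0.86 ± 0.15 (adjusted p = 0.0363), from 0.39 ± 0.34 to 1.25 ± 0.53. Both were higher on 5 of 5 slides, as the naming rule required. These were the only 2 genes past the threshold in limma, both higher, with 1456 genes at an unadjusted p under 0.05. Acute phase genes, whose products enter plasma during inflammation, rose as a list, with a mean change of 0.59 over 15 measured genes (adjusted p = 2.69e-09). All 15 were positive, and the list mean was higher on 5 of 5 slides. Of the 15, 7 rose and 0 fell adjusted over the list alone, against 0 over all genes tested. Among them were Lcn2, which encodes an iron-siderophore binding protein, at 1.25 ± 0.23 (adjusted p = 0.0524 over all genes), and the ferroxidase gene Cp at 0.81 ± 0.20 (adjusted p = 0.457). So were the serum amyloid genes Saa1 at 1.06 ± 0.28 and Saa3 at 1.92 ± 0.56 (both adjusted p = 0.71). With each of the 10 compared arrays left out in turn, Saa1 ranged from 0.591 to 1.306 and Saa3 from 1.221 to 2.308. Over the alternative settings Cp ranged from 0.513 to 0.901. Of 14 listed CXC chemokines and neutrophil-recruiting cytokines, 5 passed the filter on dim probes: Cxcl5, Il1b, Csf2, Tnf and Ppbp. They rose with a mean of 0.67 but a median of 0.42 (adjusted p = 5e-04), 5 of 5 positive. Il1b was at 0.56, Csf2 at 0.24 and Tnf at 0.205 (adjusted p from 0.712 to 0.714 over all genes). The member that rose adjusted over the list alone was Cxcl5, a neutrophil attractant, at 1.95 ± 0.42 (1 against 0 over all genes, where its adjusted p was 0.155). Cxcl5 was above background on 2 of the 5 controls, so the size of its change is uncertain, and with Agilent's processed signals it was 4.53 (0.269). NF-kB and TLR signalling genes rose with a mean of 0.20 over 17 genes (adjusted p = 0.000174), 13 positive. Relb, Bcl3, Birc3, Nfkb2, Nfkbia, Tnfaip3 and Vcam1 rose adjusted over the list alone (7 against 0 over all genes). Relb, a subunit of NF-kB, was at 0.52 ± 0.11 (adjusted p = 0.114). Without the arrays high in muscle genes the NF-kB list mean was 0.13 (0.0236) and Relb was at 0.32 (0.561), and the CXC list mean was 0.62 (0.038). These 3 lists kept their calls with an estimated correlation (adjusted p = 0.0426 each) and by themselves in fry (adjusted p = 0.00681 each). With any 1 of the 38 arrays left out they were still called at the preset correlation. With an estimated correlation, leaving out 11 of the 38 arrays in turn ended the acute phase call, among them 0 µg replicate 1 (adjusted p = 0.169), 2 (0.0843) and 3 (0.0845) and 162 µg replicate 3 (0.11). Leaving out 13 arrays in turn ended the CXC call, among them 0 µg replicate 1 (0.169), 2 (0.0843) and 3 (0.0845) and 162 µg replicate 3 (0.11) and 5 (0.0686). Leaving out 15 ended the NF-kB call, among them 0 µg replicate 1 (0.169), 2 (0.0845) and 3 (0.0859) and 162 µg replicate 1 (0.0872), 2 (0.0537) and 3 (0.11). The other arrays that did so belong to other groups and only share the estimate of spread. In the same comparison the skeletal muscle genes had a mean of -3.02, lower on 3 of 5 slides (adjusted p = 0.000505, and 0.443 with an estimated correlation). They had 5 of 6 members lower adjusted over the list alone, against 0 over all genes, and 3 of the 5 controls were among the arrays high in them. Without the 8 such arrays the mean was 0.25 (adjusted p = 0.359).

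**Figure D2:**
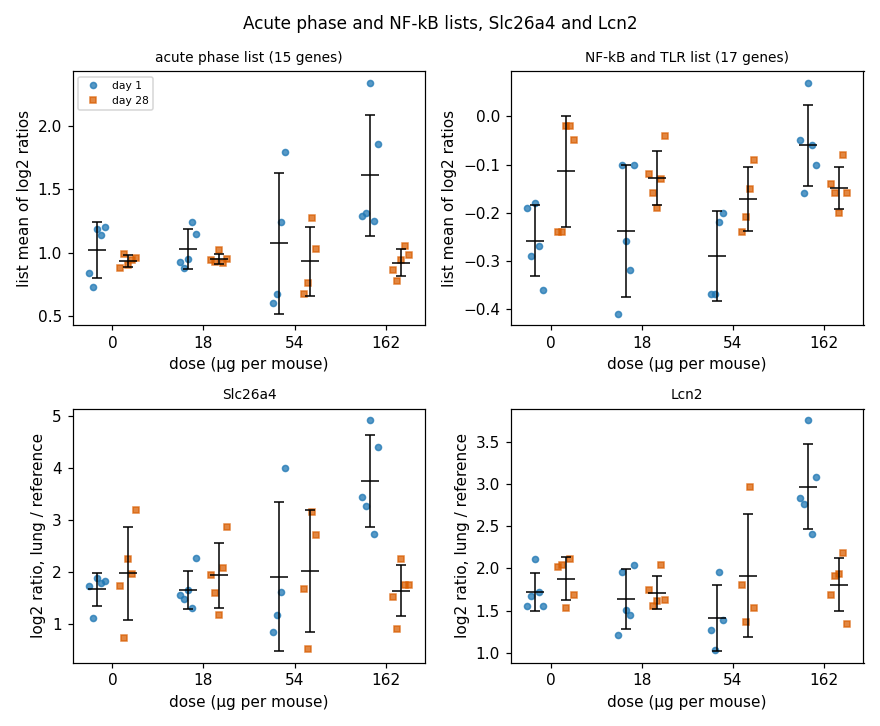
Log2 ratio of lung over reference on the y axes for the mean of 15 acute phase genes, the mean of 17 NF-kB and TLR signalling genes, Slc26a4 and Lcn2, against dose in µg per mouse on the x axes, with a dot per array (day 1 blue circles, day 28 orange squares) and bars of the mean ± SD. On day 1, Slc26a4 averaged 3.76 at 162 µg and 1.67 at 0 µg.

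The calls of single genes at 162 µg on day 1 rested on the full set of arrays. The count of 2 became 0 without 0 µg replicate 3, 4 or 5 and without 162 µg replicate 3 or 5, 1 without 162 µg replicate 1, 5 without 162 µg replicate 4 and 6 without 162 µg replicate 2. Slc26a4 missed the threshold without 0 µg replicate 3, 4 or 5 or 162 µg replicate 1, 3 or 5 (adjusted p from 0.0576 to 0.325), with changes from 1.86 to 2.18. Noxo1 missed it without 0 µg replicate 1, 2, 3, 4 or 5 or 162 µg replicate 3 or 5 (adjusted p from 0.0512 to 0.325), with changes from 0.70 to 0.93. In 10 of 18 alternative settings each gene missed the threshold, among them the fit without the 8 arrays high in muscle genes (Slc26a4 1.85, adjusted p = 0.378; Noxo1 0.92, 0.343). Slc26a4 changed by 1.65 and Noxo1 by 0.71 with the conflicting-label array placed at day 1 (0.707 each), the highest adjusted p of all settings for both.

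A further 5 lists were called at 162 µg on day 1 at the preset correlation and not with an estimated one. Lysosome and phagocytosis genes had a mean of 0.14 over 21 genes (adjusted p = 0.00815, and 0.451 with an estimated correlation). Ctsk, a cathepsin gene, rose adjusted over the list alone (1 against 0 over all genes). That call was lost without 162 µg replicate 3 (adjusted p = 0.0578) or 0 µg replicate 5 (0.0581), and without the arrays high in muscle genes (0.05, 0.722). Interferon-stimulated genes had a mean of 0.14 over 22 genes (adjusted p = 0.00552, and 0.695 with an estimated correlation), with 0 past the threshold adjusted over the list alone. They lost the call without 0 µg replicate 5 (0.0682), and without the arrays high in muscle genes the mean was -0.005 (0.841). Cell cycle genes had a mean of -0.14 over 22 genes (adjusted p = 0.00608, and 0.697 with an estimated correlation), with 0 past the threshold adjusted over the list alone. Their call was lost without 0 µg replicate 4 (-0.06, 0.169) or 5 (0.0581) or 162 µg replicate 5 (0.055), and the mean was -0.22 without 0 µg replicate 1. It was -0.02 without the arrays high in muscle genes (0.749) and 0.06 with the muscle list mean as a covariate (0.394). Club and goblet cell markers had a mean of 0.61 over 15 genes but a median of 0.19 (adjusted p = 0.0377, and 0.697 with an estimated correlation). The count adjusted over the list alone was 2, against 1 over all genes, Slc26a4. Without the arrays high in muscle genes the mean was 1.55 (5.34e-06), and with the muscle list mean as a covariate 0.90 (0.00154). The mean was 0.15 without 0 µg replicate 1 (adjusted p = 0.791). The call was also lost without 162 µg replicate 2 (0.0979), 3 (0.0578) or 5 (0.107) and without day 28 162 µg replicate 5 (0.0586). Circadian clock genes had a mean of -0.26 over 14 genes (adjusted p = 0.016, and 0.292 with an estimated correlation). Arntl rose and Hlf, Dbp and Tef fell adjusted over the list alone (1 and 3, against 0 over all genes). The clock mean was -0.45 without the arrays high in muscle genes (0.00271). That call was lost without 0 µg replicate 1 (-0.16, 0.2) or 3 (0.0507) or 162 µg replicate 1 (0.0529). Neutrophil markers (mean 0.14, adjusted p = 0.187), CC chemokines (0.18, 0.122), alveolar macrophage markers (0.10, 0.325), fibrosis and extracellular matrix genes (0.11, 0.215) and oxidative stress and metallothionein genes (-0.23, 0.187) did not pass the test.

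At the lower doses on day 1, no gene passed the threshold. At 18 µg limma called 0 genes, with 856 at an unadjusted p under 0.05 and a lowest adjusted p of 0.998. At 54 µg it called 0 genes, with 2892 at an unadjusted p under 0.05 and a lowest adjusted p of 0.237. Without the arrays high in muscle genes limma called 355 genes at 54 µg. That fit lacks 3 of the 5 day 1 controls, 2 of the 5 arrays at 18 µg and 2 of the 4 at 54 µg. Its day 1 values therefore rest on few arrays, and heart muscle and adipose genes differed strongly at 54 µg in it (below). Slc26a4 changed by -0.01 ± 0.35 at 18 µg and 0.33 ± 0.37 at 54 µg, neither past the threshold. At 18 µg, 5 lists were called, and at 54 µg 4 lists were, and 0 of these held with an estimated correlation (adjusted p = 0.931 for each list at 18 µg and 0.899 for each at 54 µg). Ciliated cell markers fell on average by 0.35 at 18 µg (14 genes, adjusted p = 0.000151), lower on 3 of 5 slides, with a mean of -0.22 without 0 µg replicate 3 and 0.02 without the arrays high in muscle genes (0.553). Club and goblet cell markers had a mean of -0.87 at 18 µg (15 genes, adjusted p = 0.00104), opposite to their change at 162 µg, and 0.30 without the arrays high in muscle genes (0.369). That call was lost without 18 µg replicate 3 (-0.54, 0.0941) or 0 µg replicate 5 (0.0951), and the mean was -1.32 without 0 µg replicate 1 and -1.31 without 18 µg replicate 1. Ciliated cell markers had a mean of -0.39 at 54 µg (adjusted p = 0.0193), lower on 2 of 4 slides. This call was lost without 54 µg replicate 1 (0.124) or 2 (0.313) or 0 µg replicate 3 (0.153) or 4 (0.0679) and without the arrays high in muscle genes (-0.12, 0.99), and the mean was -0.68 without 54 µg replicate 3. No member of either list passed the threshold at these doses, over all genes or adjusted over the list alone. At 54 µg heart muscle genes (mean 1.05, 11 of 11 positive, adjusted p = 0.0193) and adipose genes (1.46, 6 of 6 positive, adjusted p = 0.0316) were higher on 3 of 4 slides. Without the arrays high in muscle genes these means were 3.57 (8.15e-08) and 4.08 (5.84e-05). The heart muscle call was lost without 0 µg replicate 1 (0.169) or 2 (0.0621) or 54 µg replicate 2 (0.313), 3 (0.0585) or 4 (0.107), with 1.90 without 54 µg replicate 1. With any 1 of the 38 arrays left out, the heart muscle mean ran from 0.386 to 1.904. The adipose call was lost without 0 µg replicate 1 (0.196) or 2 (0.107) or 54 µg replicate 2 (0.0701), 3 (0.119) or 4 (0.354), and with the authors' table (0.0635). The adipose mean ran from 0.839 to 2.128 with any 1 of the 38 arrays left out. Without 54 µg replicate 3 the count at 54 µg was 1348 genes. Without 0 µg replicate 1 it was 1 at 54 µg and 2 at 18 µg.

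The step from 54 to 162 µg at day 1 held the largest count of the 14 contrasts, 176 genes, 101 higher and 75 lower, of which 115 also differed by 1.5-fold. Lcn2 was higher at 162 µg by 1.496 ± 0.246 (adjusted p = 0.0131), Cxcl5 by 1.95 ± 0.45 and Slc26a4 by 1.75 ± 0.37 (both adjusted p = 0.0495), on 4 of 4 slides each. Cxcl5 was above background on 1 of the 4 arrays at 54 µg. Lower were Cpt1b, the muscle form of a carnitine palmitoyltransferase, at -2.39 ± 0.56, Art5, an ADP-ribosyltransferase, at -2.22 ± 0.53, and Trim72, a membrane repair gene of striated muscle, at -2.15 ± 0.52 (each adjusted p = 0.0495, 4 of 4 slides). Trim72 was above background on 1 of the 5 arrays at 162 µg. Of genes chosen after their values were seen, Noxo1 was higher by 1.03 ± 0.16 (adjusted p = 0.0107) and the surfactant lipid transporter gene Abca3 by 0.72 ± 0.18 (0.0499). The respiratory chain genes Uqcrc1 (-1.35 ± 0.31) and Ndufv1 (-1.14 ± 0.28), chosen in the same way, were lower (both 0.0495). In the same contrast skeletal muscle genes had a mean of -3.19 (adjusted p = 0.00394, and 0.668 with an estimated correlation), lower on 4 of 4 slides. Of the 6, 5 were lower adjusted over the list alone against 0 over all genes. Heart muscle genes (mean -1.35, adjusted p = 0.00394) and adipose genes (-1.55, 0.0305) were also called lower, with an adjusted p of 0.694 each with an estimated correlation. Acute phase genes had a mean of 0.49 (adjusted p = 0.0149, and 0.668 with an estimated correlation), with 6 higher adjusted over the list alone against 2 over all genes, Lcn2 and Cp. The call was lost without 54 µg replicate 1 (0.0697) or 2 (0.0564). Alveolar type II cell and surfactant genes had a mean of 0.37, 14 of 14 positive (adjusted p = 0.0263, and 0.694 with an estimated correlation), with 3 higher adjusted over the list alone against 1 over all genes. They lost the call without 162 µg replicate 1 (0.0616) or 54 µg replicate 2 (0.0577) or 4 (0.0679). In all 9 lists were called, 0 with an estimated correlation. Limma called 0 genes for the step from 18 to 54 µg, with 508 at an unadjusted p under 0.05, and 1 without 54 µg replicate 4.

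The count of 176 at the upper step moved with almost every array of the groups. It was 646 without 54 µg replicate 1, 4460 without 54 µg replicate 3, 0 without 54 µg replicate 2 and 2 without 54 µg replicate 4. It was 1, 3, 1, 7 and 0 without 162 µg replicate 1, 2, 3, 4 and 5. Lcn2, Cxcl5, Slc26a4, Cpt1b, Art5 and Trim72 stayed past the threshold without 54 µg replicate 1 or 3. Lcn2 missed it without 162 µg replicate 1, 3 or 5 or 54 µg replicate 2 or 4 (adjusted p from 0.0525 to 0.228). Slc26a4 missed it without 162 µg replicate 1, 2, 3 or 5 or 54 µg replicate 2 (0.0804 to 0.252). Cxcl5, Cpt1b, Art5 and Trim72 missed it without 162 µg replicate 1, 2, 3, 4 or 5 or 54 µg replicate 2 or 4 (0.0725 to 0.252). With the muscle list mean as a covariate or with arrays high in muscle genes left out, the counts were 0 and 1. Lcn2 missed the threshold in 6 of 18 alternative settings, Cpt1b and Slc26a4 in 10 of 18, Cxcl5 in 10 of 17, and Art5 and Trim72 in 11 of 17. With Agilent's processed signals the split was 219 higher and 104 lower, and the median of all genes moved by 0.114.

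The late response to the highest dose was compared with vehicle at day 28. Genes that glucocorticoids induce were higher at 162 µg. Tsc22d3 (NM_001077364), which encodes the glucocorticoid-induced leucine zipper, rose by 1.51 ± 0.27 (adjusted p = 0.0254), from 1.61 ± 0.35 to 3.11 ± 0.36 (SD, n = 5 each). Klf9 (NM_010638), a Krüppel-like transcription factor, rose by 0.71 ± 0.13 (adjusted p = 0.0254). The list of 9 such genes rose with a mean of 0.72 (adjusted p = 3.3e-08, and 0.0474 with an estimated correlation), 7 of 9 positive and higher on 5 of 5 slides. Errfi1, Fkbp5, Zbtb16 and Cdkn1a also rose adjusted over the list alone (6 in all, against 2 over all genes). Its member Lcn2, also on the acute phase list, was at -0.07 ± 0.23. The list mean was lowest in the day 28 controls, at 0.48 ± 0.07, against 1.20 ± 0.28 at 162 µg on day 28 (SD, n = 5 each). It was 0.94 ± 0.41 in the day 1 controls (SD, n = 5) and 0.90 to 1.00 in the exposed groups of day 1. The clock gene Per1 (NM_011065) rose by 1.65 ± 0.33 (adjusted p = 0.0365), from 0.39 ± 0.48 to 2.03 ± 0.43. Circadian clock genes as a list had a mean of 0.31 over 14 genes, 12 positive (adjusted p = 0.000863, and 0.0763 with an estimated correlation). Per1 and Per3 were higher adjusted over the list alone (2 against 1 over all genes). Rises were also found in Csrnp1 (1.51 ± 0.30, adjusted p = 0.0365) and Fosl2 (0.69 ± 0.13, adjusted p = 0.0308), which encode nuclear transcription regulators. So they were in the dual specificity phosphatase gene Dusp8 (0.72 ± 0.14, 0.0365), and in the constitutive chaperone gene Hspa8 (0.68 ± 0.13, 0.0308). The cyclic AMP phosphodiesterase gene Pde4d rose by 0.66 ± 0.11 (0.0213; 0.28 as the mean of its probes, 0.194), the protein kinase gene Pkn2 by 0.66 ± 0.13 (0.0308) and the sodium pump subunit gene Atp1b1 by 0.63 ± 0.11 (0.0213), while Thap3 fell by 0.39 ± 0.07 (0.0254). Each of these 11 genes had the same sign on 5 of 5 slides, as the naming rule required. In all limma called 13 genes, 11 higher and 2 lower, with 1886 at an unadjusted p under 0.05. The count was 51 without the arrays high in muscle genes, 87 without those apart on the first principal component, 144 with array weights, 44 with only the compared groups and 25 and 35 with the covariates. None of the day 28 arrays at 0 or 162 µg was among those high in muscle genes (list means -0.39 ± 0.16 and -0.47 ± 0.08, SD, n = 5).

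**Figure D3:**
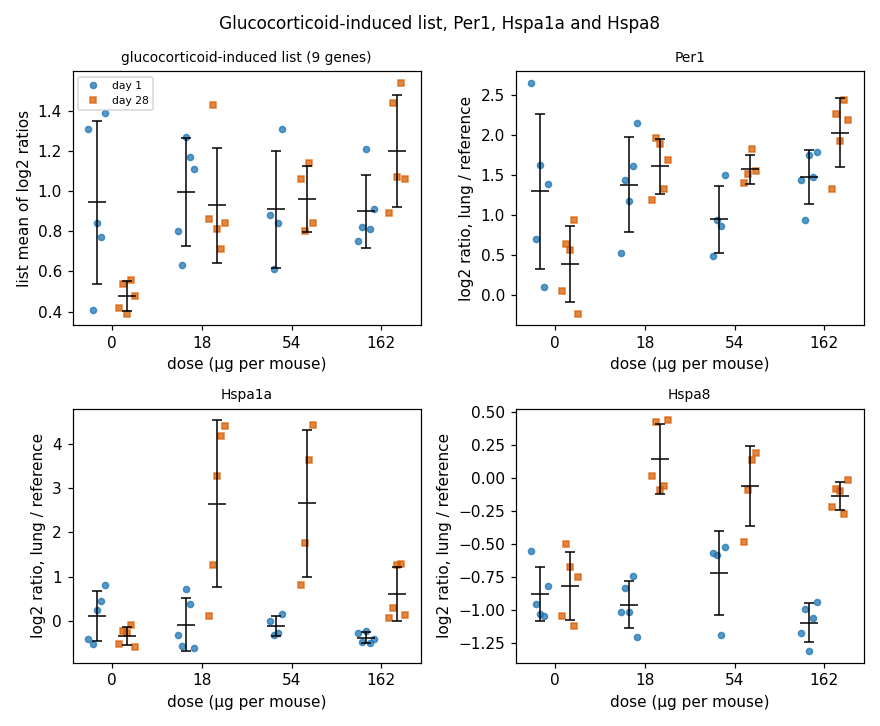
Log2 ratio of lung over reference on the y axes for the mean of 9 glucocorticoid-induced genes, Per1, Hspa1a and Hspa8, against dose in µg per mouse on the x axes, with a dot per array (day 1 blue circles, day 28 orange squares) and bars of the mean ± SD. On day 28 Per1 averaged 2.03 at 162 µg and 0.39 at 0 µg, and Hspa1a averaged 2.65 at 18 µg and -0.35 at 0 µg.

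The 13 calls at 162 µg on day 28 also rested on the full set of arrays. The count was 0 without 0 µg replicate 1, 3 or 5 or 162 µg replicate 3, 4 or 5, and 3 without 162 µg replicate 2. Without the same arrays, except 162 µg replicate 2 for Pde4d, Atp1b1 and Thap3, each of the 11 named genes missed the threshold, with adjusted p from 0.0565 to 0.251. Per1 and Csrnp1 also missed it without 0 µg replicate 2 (0.0544 and 0.0895), and Dusp8 without 0 µg replicate 2 (0.0825) or 162 µg replicate 1 (0.0897). Hspa8 missed it without 162 µg replicate 1 (0.0506) or 0 µg replicate 4 (0.087) and Pkn2 without 0 µg replicate 4 (0.0536). The glucocorticoid-induced and clock lists were still called at the preset correlation with any 1 of the 38 arrays left out. With an estimated correlation, leaving out 25 of the 38 in turn ended the glucocorticoid-induced call, among them 0 µg replicate 1 and 3 (0.0963 each) and 4 (0.0552) and 162 µg replicate 2 (0.152) and 4 (0.141). The others belong to other groups (0.0521 to 0.0687). With the conflicting-label array (162 µg replicate 5) placed at day 1, 0 genes were called, and the 11 named genes had adjusted p from 0.0969 (Tsc22d3, Klf9 and Atp1b1) to 0.305 (Dusp8 and Pkn2). Thap3 missed the threshold in 5 of 18 alternative settings, Dusp8, Pde4d and Pkn2 in 4, Per1, Csrnp1 and Hspa8 in 3, and Fosl2 in 2.

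Other lists at 162 µg on day 28 were called at the preset correlation alone. Club and goblet cell markers fell by a mean of 0.99 over 15 genes, with 0 of 15 positive and lower on 4 of 5 slides (adjusted p = 0.000863, and 0.683 with an estimated correlation). None (0) fell adjusted over the list alone, and Clca1, a goblet cell gene, was at -3.62 ± 1.39 (adjusted p = 0.4). Clca1 was above background on 2 of the 5 arrays at 162 µg and 4 of the 5 controls, so the size of this change is uncertain. The mean was -1.49 without 0 µg replicate 4 and -0.71 without 162 µg replicate 5, which ended the call (0.099). Monocyte and recruited macrophage markers had a mean of -0.18 over 16 genes (adjusted p = 0.0429, and 0.387 with an estimated correlation), with 0 past the threshold adjusted over the list alone. That call was lost without 0 µg replicate 3 (0.122) or 5 (0.0539), 162 µg replicate 4 (0.0636) or 5 (0.098), day 1 54 µg replicate 1 (0.0505) or day 28 54 µg replicate 3 (0.0521), and with no slide block (0.0893). Acute phase genes had a mean of -0.02 and a median of 0.03 (adjusted p = 0.833), neutrophil markers a mean of -0.21 (0.176), fibrosis and extracellular matrix genes 0.11 (0.123) and alveolar macrophage markers -0.07 (0.917).

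At 18 and 54 µg on day 28, Hspa1a (NM_010479), the inducible HSP70 gene, had the highest fold change of the called genes. It rose by 3.00 ± 0.48 at 18 µg (adjusted p = 0.00404), from -0.35 ± 0.20 to 2.65 ± 1.89 (SD, n = 5), and by 3.12 ± 0.52 at 54 µg (adjusted p = 0.00596), to 2.67 ± 1.67 (SD, n = 4). It was above background on 4 of the 5 controls. At 162 µg it was at 0.95 ± 0.48 (adjusted p = 0.585), and its difference between 162 and 54 µg was -2.16 ± 0.52 (adjusted p = 0.812). At 18 µg the HSP40 gene Dnajb1 rose by 1.67 ± 0.28 (0.00538) and the HSP110 gene Hsph1 by 1.23 ± 0.20 (0.00404). Id2, an inhibitor of DNA binding, fell by 0.77 ± 0.16 (0.0426). Each had its sign on 5 of 5 slides, as the naming rule required. At 54 µg Dnaja1, another HSP40 gene, rose by 0.93 ± 0.19 (0.0333), Dusp8 rose by 0.74 ± 0.15 (0.0333) and 1700052K11Rik fell by 0.50 ± 0.09 (0.00913), each on 4 of 4 slides. Of genes chosen after their values were seen, Dnaja1 rose by 1.22 ± 0.18 (0.0014), Hspa8 by 0.97 ± 0.13 (0.000855) and the HSP90 co-chaperone gene Chordc1 by 0.63 ± 0.09 (0.0014) at 18 µg. At 54 µg, chosen likewise, Hspa8 rose by 0.72 ± 0.14 (0.0259) and Chordc1 by 0.52 ± 0.10 (0.0245). Limma called 19 genes at 18 µg, 15 higher and 4 lower, with 1544 at an unadjusted p under 0.05. At 54 µg it called 23 genes, 11 higher and 12 lower, with 1497 at an unadjusted p under 0.05. The array at 54 µg that was high in muscle genes was 1 of 4. Without the 8 such arrays, all 19 calls at 18 µg and 21 of the 23 at 54 µg remained.

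The glucocorticoid-induced list was also higher than in the day 28 controls at the lower doses of that day, at the preset correlation. Its mean was 0.45 at 18 µg (adjusted p = 0.00168, and 0.408 with an estimated correlation) and 0.48 at 54 µg (0.00162, and 0.484 with an estimated correlation). At these doses 4 and 3 of 9 were higher adjusted over the list alone, against 0 over all genes. It was higher on 5 of 5 and 4 of 4 slides, and the call at 18 µg was lost without 18 µg replicate 2 (0.29, adjusted p = 0.0514). The list mean was 0.93 ± 0.29 at 18 µg and 0.96 ± 0.17 at 54 µg (SD, n = 5 and 4). These values lay near the 0.94 ± 0.41 of the day 1 controls, while the day 28 controls were low at 0.48 ± 0.07 (SD, n = 5 each). A low control group and a rise with dose cannot be told apart here. At 18 µg cholesterol synthesis genes had a mean of -0.19 over 17 genes, 0 positive (adjusted p = 0.00163, and 0.936 with an estimated correlation). Cell cycle genes had a mean of -0.19 over 22 genes, 0 positive (0.000603, and 0.936 with an estimated correlation). The cell cycle mean was -0.11 without 0 µg replicate 1, and its call was lost without 18 µg replicate 3 (0.0562). CC chemokines had a mean of -0.23 (0.0135, and 0.408 with an estimated correlation), with Ccl4 and Ccl12 lower adjusted over the list alone and 0 over all genes. That call was lost without 0 µg replicate 2 (0.059) or 18 µg replicate 3 (0.0965) or 5 (0.0513). At 54 µg markers of NK and cytotoxic cells had a mean of -0.30 over 11 genes, 0 positive (0.00258, and 0.874 with an estimated correlation), lower on 4 of 4 slides. None of the cholesterol, cell cycle or NK genes passed the threshold adjusted over the list alone.

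Single arrays also moved the counts at the lower doses of day 28. At 18 µg the count of 19 was 12, 11 and 10 without 0 µg replicate 1, 3 and 5, and 9 and 8 without 18 µg replicate 4 and 5. Hspa1a, Dnajb1 and Hsph1 stayed past the threshold with any 1 of the 10 arrays left out, and missed it with only the compared groups in the fit (0.12, 0.0937 and 0.0937). Id2 stayed past it only without 18 µg replicate 1 (otherwise adjusted p from 0.0596 to 0.224 without 0 µg replicate 1 to 5 or 18 µg replicate 2 to 5), and missed it in 5 of 18 alternative settings. At 54 µg the count of 23 was 13, 8 and 5 without 0 µg replicate 1, 3 and 5, 76 without 54 µg replicate 1, and 3 without 54 µg replicate 2 or 4. Hspa1a missed the threshold without 54 µg replicate 4 (2.62, adjusted p = 0.0939) and with only the compared groups in the fit (0.542). Dnaja1 missed it without 0 µg replicate 1, 3 or 5 or 54 µg replicate 2, 3 or 4 (0.0895 to 0.196), and Dusp8 without 0 µg replicate 1, 2, 3 or 5 or 54 µg replicate 1, 2 or 4 (0.0645 to 0.185). The fall of 1700052K11Rik was lost without 54 µg replicate 2 (0.108) or 4 (0.0519) or 0 µg replicate 5 (0.0773). Dusp8 missed the threshold in 4 of 18 alternative settings, Dnaja1 in 3 and 1700052K11Rik in 2.

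Doses at day 28 shared called genes, and they also shared their 5 control arrays. The 18 and 54 µg lists shared 8 genes, the 18 and 162 µg lists 3 and the 54 and 162 µg lists 4, all with the same sign. At all 3 doses 3 genes were called. Independent lists of these sizes would share 0.00763, 0.00763 and 0.00559 higher genes. With the residuals of the fit dealt out anew among the arrays 100 times and the controls still shared, which leaves no effect and few calls, a mean of 0, 0 and 0.01 genes was shared. The covariance of the 18 and 162 µg changes over all genes was 0.0202, against a mean of 0.0214 (-0.0158 to 0.0925) with dealt-out residuals. With the 5 controls split into 2 and 3 in all 20 ways, so that doses shared no control, the covariance averaged 0.00971 (0.00362 to 0.0132) for 18 and 162 µg. It averaged 0.0062 for 18 and 54 µg and 0.00906 for 54 and 162 µg. With dealt-out residuals the mean over the 3 pairs (0.00832 observed) ran from -0.0414 to 0.0625. In these splits 0 to 1 called genes were shared. Genes ranked first for a dose against part of the controls, as many as were called, changed in the same direction by a mean of 0.43 at another dose against the other controls. With dealt-out residuals, and 1 split per set in place of the mean over 20, this ran from -0.72 to 0.60 and was as large in 1 of 100 sets. Directly compared, no gene passed the threshold between doses at day 28. From 18 to 54 µg limma called 0 genes (641 at an unadjusted p under 0.05; 1 without 54 µg replicate 1 or 3), and from 54 to 162 µg 0 genes (715; 4 without 54 µg replicate 1).

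The responses at day 28 and day 1 were compared through the difference of the changes from the controls of each day. A position effect common to all doses of a day cancels in this difference, but one that differed between doses would not. Slc26a4 had a response 2.42 ± 0.49 lower at day 28 than at day 1 (adjusted p = 0.209), and Cxcl5 one 2.48 ± 0.60 lower (0.409); neither passed the threshold. The response of CXC chemokines and neutrophil-recruiting cytokines to 162 µg fell from day 1 to day 28 by a mean of 0.90 over the 5 tested genes (adjusted p = 0.000204, and 0.0395 with an estimated correlation). The median of these differences was -0.54. Cxcl5 was lower adjusted over the list alone (1 against 0 over all genes). The response of circadian clock genes rose by 0.57 over 14 genes (adjusted p = 1.9e-05, and 0.0226 with an estimated correlation). Of these, 8 were higher and 1 lower adjusted over the list alone, against 0 over all genes. Dbp was at 2.05 ± 0.69 and Arntl at -1.13 ± 0.41. In the controls alone the clock list was 0.38 lower at day 28 than at day 1, which makes up the larger part of this rise. Both lists were called at the preset correlation with any 1 of the 38 arrays left out. With an estimated correlation the clock call was lost without day 1 0 µg replicate 3 (0.0528). The CXC call was lost when each of 15 arrays was left out in turn (adjusted p from 0.0506 to 0.0852): 0 µg replicate 1, 3 or 5 and 162 µg replicate 3 or 5 of day 1, 0 µg replicate 1, 2 or 3 and 162 µg replicate 1, 2 or 4 of day 28, and 4 arrays at 54 µg. The acute phase response was lower by 0.61 (4.25e-05, and 0.14 with an estimated correlation) and the glucocorticoid-induced response higher by 0.77 (2.36e-05, and 0.109 with an estimated correlation). In the controls alone the glucocorticoid-induced list was 0.47 lower at day 28 than at day 1, which makes up the larger part of its rise. At 162 µg its mean was 0.90 ± 0.18 on day 1 and 1.20 ± 0.28 on day 28 (SD, n = 5 each). In all 15 lists were called at 162 µg, 2 of them with an estimated correlation. Skeletal muscle genes, high on 3 of the 5 day 1 controls, differed in the same contrast by 2.94 (0.019, and 0.483 with an estimated correlation). This call was lost without day 1 0 µg replicate 3 (0.0506), 4 (0.0678) or 5 (0.0775). Limma called 0 single genes at 162 µg (1481 at an unadjusted p under 0.05; 1 without day 28 0 µg replicate 2). It called 0 at 54 µg (1028; 7 without day 28 54 µg replicate 1) and 0 at 18 µg (723; 1 without day 28 18 µg replicate 1 or day 1 18 µg replicate 4, 2 without day 28 18 µg replicate 3). Of the 2 genes called higher at day 1 and the 11 at day 28 at 162 µg, 0 were shared, where 0.00102 would be by chance (Fisher exact p = 1).

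Control lungs were compared between days to show the background against which the responses were read. Day and position on the slide cannot be told apart in this comparison. Clock genes were lower in day 28 controls by a mean of 0.38 over 14 genes (adjusted p = 1.02e-05, and 0.0232 with an estimated correlation), on 5 of 5 slides. Of these, 9 were lower and 1 higher adjusted over the list alone, against 0 over all genes. Dbp, an output gene of the clock, was at -1.48 ± 0.49, Per1 at -0.91 ± 0.33 and Arntl, which encodes the activator BMAL1, at 0.64 ± 0.29. With an estimated correlation the call was lost without day 1 0 µg replicate 1 (0.229), 2 (0.087) or 3 (0.105) or day 28 0 µg replicate 5 (0.0794). Glucocorticoid-induced genes were lower by 0.47 on average (adjusted p = 0.000234, and 0.183 with an estimated correlation) and interferon-stimulated genes were higher by 0.21 (3.12e-07, and 0.183 with an estimated correlation). Skeletal muscle genes were lower by 3.06 in the same contrast (0.000234, and 0.262 with an estimated correlation). In all 11 lists were called, 1 with an estimated correlation. Limma called 0 genes, with 1097 at an unadjusted p under 0.05. Without day 1 0 µg replicate 2 it called 2.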

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

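The tests of explanations below were chosen only after the results were seen, except the comparison of covariances under shared controls with dealt-out residuals and the counts over 100 splits, which were planned; leaving out arrays and covariates for muscle genes were also added later. On day 1 control replicate 2 stood apart from its group in 2 measures: its Slc26a4 log2 ratio was 1.12 against 1.74 to 1.88 on the other controls, and it had 21661 red spots above background against 31534 to 34887. It lies on slide 2, the dimmest slide. These were 2 of 85 groups looked at, and chance alone sets apart about 1 in 20 groups. The response to 162 µg differed between days for the CXC chemokine list (-0.90, adjusted p = 0.0395 with an estimated correlation) and for the circadian clock list (0.57, 0.0226); 23 list responses differed by camera at the preset correlation and 2 with an estimated one.

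Skeletal muscle transcripts stood out on part of the arrays. RNA of another tissue carried with the lung pieces may account for this: all 8 arrays above the cutoff were also the 8 highest on a second list of 10 striated muscle genes, at 2.80 or more against at most 2.24 elsewhere, and 6 of them were also high in squamous epithelium genes. Scanner, dye or spot signal remained open, since the green range of the muscle list was 0.286 of the red range (0.372 before centring on the array median), between the bounds of 0.25 and 0.5 set for either answer. A real difference between dose groups on day 1 also cannot be told apart with these group sizes (permutation test, p = 0.216). The tables argue against such arrays as the source of the acute phase shift at 162 µg on day 1, which without them still had an adjusted p of 3.24e-08; the NF-kB list mean fell from 0.20 to 0.13 (0.0236).

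The step from 54 to 162 µg at day 1 may owe part of its 176 calls to the same arrays. With the muscle list mean as a covariate, the median difference of the called genes was 0.707 of its former size, from 0.68 to 0.48 (log2), with a median SE of 0.157 before and 0.152 after. All of the calls ended, but shrinkage does not account for each: Lcn2 went from 1.496 to 1.335, Slc26a4 from 1.75 to 1.60 and Cxcl5 from 1.95 to 2.06 (adjusted p = 0.257, 0.411 and 0.411 with the covariate). For the called genes as a set, other-tissue RNA and dose cannot be told apart, as 2 of the 4 arrays at 54 µg and 0 of the 5 at 162 µg were high in muscle genes. Heart muscle (-1.35), adipose (-1.55) and brown fat genes (-1.765) were also lower on average at 162 µg. RNA of those tissues was not tested, as the covariate held skeletal muscle genes only. Lcn2, Slc26a4 and Cxcl5 kept most of their difference with the covariate.

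At day 28, heat shock, glucocorticoid-induced and clock genes differed from the controls at 1 or more doses. The tables argue against RNA of skeletal muscle or squamous epithelium, whose list means reached at most 0.19 on any day 28 array at 0, 18 or 162 µg. At 54 µg 91.3% of the 23 calls stayed past the threshold without the arrays high in muscle genes. Heart muscle list means were 2.32 ± 1.13, 2.15 ± 1.29 and 2.28 ± 0.65 at 0, 18 and 162 µg (SD, n = 5 each), and RNA of heart muscle was not tested. The other values bear on adipose RNA and on the shared controls. The tables argue against adipose RNA as the whole cause, since 96.4% of the 55 calls at the 3 doses stayed with the adipose list mean as a covariate. They also argue against chance values of the shared controls, for the genes ranked first in each split of the controls rather than for the called genes themselves. Genes ranked first for a dose against part of the controls changed by a mean of 0.43 at another dose against the other controls. A change as large was found in 1 of 100 sets of dealt-out residuals (highest 0.60). The 0.43 is a mean over 20 splits of the controls, while each dealt-out set used 1 split. A systematic difference of the control mice, as opposed to chance values, would pass this test. Over all genes the covariance of 0.0202 lay within the dealt-out range (-0.0158 to 0.0925, other pairs 0.0197 and 0.0167). With no control shared, 0.00832 (mean of the pairs) did so too (-0.0414 to 0.0625). Over all genes a likeness of the doses beyond shared controls therefore stays open. Another time of day at collection for the control mice alone would move all doses alike. The DBP and PER arm minus the BMAL1 arm of the clock shifted by -0.539 ± 0.327 at 18 µg, but by 0.362 ± 0.35 at 54 µg and 0.485 ± 0.327 at 162 µg (SE). This runs against a shift of the controls alone at 18 µg without excluding it (permutation test of equal doses within slides, p = 0.0598). An F test, computed first and replaced because the groups are small, gave 0.00886. Between the 54 and 18 µg groups the arms differed by 0.901 ± 0.35 (SE). Collection times that differed between dosed groups are not covered by this test. Time of day at collection therefore cannot be told apart from an effect of the particles, as the labels give no collection times. The sample numbers of the day 28 controls ran from 50 to 426, against 335 to 353 for the exposed day 28 groups. Whether the controls came from another set of animals or another date is not stated, and this cannot be told apart from dose either.

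Other splits of the same arrays into groups of the same sizes were counted with limma, 100 per comparison, the real one included. These splits mix arrays of different slides. At 18 µg on day 28, 1 of 100 splits called as many as the real 19 (highest other 1). The share was also 1 of 100 at 54 µg (real 23, highest other 4) and at 162 µg on day 28 (real 13, highest other 0). Such counts were thus rare among splits that mix slides, which does not settle chance within slides. At 162 µg on day 1, 3 of 100 splits called as many as the real 2, but the highest other split called 17, and so few calls are weak ground for excluding chance. Swapping groups within slides leaves 16 splits, too few for a share under 0.05. The highest other counts among these were 0 at 162 µg on day 1, 1, 2 and 0 at 18, 54 and 162 µg on day 28 (real 2, 19, 23 and 13), and 284 for 162 against 54 µg on day 1 (real 176). For 162 against 54 µg on day 1, 5 of 100 splits called as many as the real 176, so chance cannot be excluded (highest other 1985). Where the real count was 0, all 100 splits give as many whatever the data, so these counts decide nothing about chance. The highest other counts there were 5348 for 18 µg and 4537 for 54 µg on day 1, 3600 for 54 against 18 µg on day 1, 69 for the same step on day 28, 4 for 162 against 54 µg on day 28, 1 for the control lungs, and 368, 346 and 30 for the differences between days at 18, 54 and 162 µg. Splits of the day 1 arrays that call several times the real count point to a structure of the samples apart from dose.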

How the results depend on the processing

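Leaving out the arrays high in muscle genes, leaving out the arrays apart on the first principal component, the covariates and the array weights were chosen only after the results were seen; all other alternatives were planned. Counts are genes past the threshold, each beside the reported 0 and 0 at 18 and 54 µg on day 1, 2 at 162 µg on day 1, 19, 23 and 13 at 18, 54 and 162 µg on day 28, and 176 for 162 against 54 µg on day 1; counts not named stayed within 1.5 times. Unless said, the cause was not tested. With no slide block they were 0 at 162 µg on day 1, 14 at 54 µg and 8 at 162 µg on day 28, and 3 for the step. With the slide as a random block (correlation 0.157) they were 0 at 162 µg on day 1, 37 at 54 µg on day 28 and 939 for the step. The step gave 527 with no background correction, 323 with Agilent's processed signals, 6 with the mean of a gene's probes and, by construction, 115 with calls that were also 1.5-fold. With no filter on dim probes (36799 genes tested) the counts were 0 at 162 µg on day 1 and 2 for the step. With probes above background on all arrays (14161 genes) they were 15 at 54 µg on day 28 and 1033 for the step. With the authors' table they were 1 at 162 µg on day 1, 438 for the step and 1 between control lungs. With only the groups compared, which leaves fewer arrays to estimate the spread, they were 0 at 162 µg on day 1, 4, 0 and 44 at 18, 54 and 162 µg on day 28, and 1 for the step. With the array of conflicting labels placed at day 1 they were 0 at 162 µg on day 1, 12 at 18 µg and 0 at 162 µg on day 28, and 0 for the step. Robust moderation with a trend gave 4 at 162 µg on day 1 and 11 for the step. Quantile normalization of the average intensity moves no ratio and so tests nothing about them.

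Leaving out the 8 arrays high in muscle genes removes 3 of the 5 controls, 2 of the 5 arrays at 18 µg and 2 of the 4 at 54 µg on day 1. On day 28 it removes 1 of the 4 at 54 µg. Counts that involve day 1 therefore rest on few arrays in this fit. Without these 8 arrays the counts were 355 at 54 µg and 0 at 162 µg on day 1, 56, 83 and 51 at 18, 54 and 162 µg on day 28, 1 for the step, 1 for 54 against 18 µg on day 28 and 19 for the difference between days at 54 µg. With the muscle list mean as a covariate they were 0 at 162 µg on day 1, 48, 51 and 25 on day 28, 0 for the step and 1 for the difference between days at 18 µg. With muscle and squamous list means as covariates they were 0 at 162 µg on day 1, 69, 60 and 35 on day 28, 0 for the step and 1 for the difference between days at 18 µg. Without the 9 arrays apart on the first principal component, which leaves a lone array at 54 µg on day 1 that is assumed to vary like the other groups, they were 3 at 54 µg and 0 at 162 µg on day 1, 82, 122 and 87 on day 28, 0 for the step, 5 for 54 against 18 µg on day 1, 1 for each step on day 28 and 2 for the difference between days at 162 µg. Array weights (0.281 to 2.86) gave 5 at 162 µg on day 1, 214, 106 and 144 on day 28, 1652 for the step, 2 for 54 against 18 µg and 6 for 162 against 54 µg on day 28. All 13 calls at 162 µg on day 28 were kept without the muscle arrays, with either set of covariates and without the arrays apart on the first component.

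Some changes at 162 µg on day 1 reversed: without the muscle arrays Csf2 (-0.02), Ifit1 (-0.029), Tnnt3 (0.63) and the interferon-stimulated (-0.005) and skeletal muscle (0.25) lists. With the muscle covariate so did Ccnb1 (0.006), Tnnt3 (0.22) and the cell cycle list (0.056), and with both covariates Csf2 (-0.003) and Tnnt3 (0.19). Without the muscle arrays the B cell (-0.056), ciliated cell (0.018) and club and goblet cell (0.30) lists also reversed at 18 µg and the interferon-stimulated list (-0.008) at 54 µg on day 1. For the skeletal muscle list and Tnnt3, leaving out the arrays chosen on those genes shows the cause by construction. Of 84 list calls over all contrasts, 7 remained with an estimated correlation.

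Leaving out each array in turn gave 0 to 2 calls at 18 µg, 0 to 1348 at 54 µg and 0 to 6 at 162 µg on day 1, and 8 to 28 at 18 µg, 3 to 76 at 54 µg and 0 to 17 at 162 µg on day 28. It gave 0 to 2, 0 to 7 and 0 to 1 for the differences between days at 18, 54 and 162 µg, 0 to 1 for 54 against 18 µg and 0 to 4460 for 162 against 54 µg on day 1, and 0 to 1 and 0 to 4 for the same steps on day 28. It gave 0 to 2 between control lungs, 0 to 0 for the overlap of days and 76 to 106 list calls. For the 27 calls of genes named by the rule, 158 of 260 such runs lost the call. For the 48 example values not past the threshold, 2 of 480 runs gained one. Of 1178 runs for lists, 1116 kept both sign and call, 62 lost the call and 0 reversed, all at the preset correlation. The runs for lists left out every array of the study in turn, and most of these lay outside the groups compared. Such arrays bear on a list mainly through the estimate of spread. The runs for genes left out only arrays of the groups compared, so the shares for lists and genes cannot be set side by side. The conflicting-label placement and the fit of only the groups compared ended 21 and 20 of the 27 calls of genes named by the rule. No paired analysis was possible because the sample numbers in the labels are not shared between groups; the slide was the block instead. Signal over background limits dim genes: Cxcl5 was above background on 1 of 4 arrays at 54 µg on day 1 and Trim72 on 1 of 5 at 162 µg, so their fold changes rest partly on background.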

Other observations

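Of the tests in this part, those of the chaperone and brown fat lists and of the arms of the clock were chosen only after the data were seen. Chaperone genes as a list (19 measured, chosen after the named heat shock genes were seen, so their direction is not independent evidence) had mean changes at day 28 of 0.72 at 18 µg, 0.55 at 54 µg and 0.25 at 162 µg, with 19, 18 and 14 genes positive and 6, 4 and 1 past the threshold over all genes tested. The list mean was -0.38 ± 0.13 in controls, 0.33 ± 0.26 at 18 µg, 0.16 ± 0.28 at 54 µg and -0.13 ± 0.07 at 162 µg (SD; n = 5, 5, 4 and 5). On day 1 its mean change was 0.12 at 54 µg and -0.06 at 162 µg, with 0 genes past the threshold. Brown fat genes (6 measured) had a mean change of 1.13 at 54 µg and -0.63 at 162 µg on day 1, with 0 past the threshold. From 54 to 162 µg on day 1 their mean was -1.765, with 0 of the 6 positive and 1 past the threshold.

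The clock list was divided into 8 genes of the DBP and PER arm and 4 genes of the BMAL1 arm, which peak at opposite times of day. At 162 µg on day 1 the arms shifted by -0.59 and 0.36, a difference of -0.95 ± 0.33 (SE). At 162 µg on day 28 they shifted by 0.49 and 0.01. In day 28 controls against day 1 controls they shifted by -0.73 and 0.22, a difference of -0.945 ± 0.327.

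Sample numbers in the labels ran from 3 to 379 for the day 1 controls and from 50 to 426 for the day 28 controls, spread at equal steps. The numbers of each exposed group were consecutive or nearly so (302 to 306 at 162 µg on day 1 and 349 to 353 at 162 µg on day 28). It is not stated whether control and exposed mice were handled apart. A difference of animal set or date would enter every comparison with 0 µg and could not be told apart from dose there. The array with conflicting labels had an acute phase list mean of 0.98, against 0.92 ± 0.10 for the 162 µg group of day 28 and 1.61 ± 0.48 for that of day 1 (SD, n = 5; the array itself is part of the day 28 group). Among entries without a symbol, the nuclear RNA entry named NEAT2 on the array was at -1.55 ± 0.29 at 54 µg on day 28 (adjusted p = 0.0211), chosen after its value was seen.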
